A study of Mus musculus with 16 samples.

How the data were processed

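The series was read as 16 mouse libraries in 4 groups of 4. These were placenta, fetal brain and maternal brain of wildtype pregnancies on day 15, and placenta of pregnancies with a conditional knockout of FOXA2 in the uterus (FOXA2 cKO). Per the labels, the knockout pregnancies were given recombinant leukemia inhibitory factor (LIF) at 10 µg per injection on day 4 to rescue implantation. Whether wildtype pregnancies had LIF was not given in the sources used here, and if they had none, genotype and LIF treatment are not separated in these samples. Total RNA was made into libraries with a stranded kit that removes ribosomal RNA. The submitters' processing notes name FastQC, HISAT2 2.0.3, featureCounts and edgeR on GRCm38.p5. The strand setting, the gene annotation and the counting options were not given in the sources used here.

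The count tables deposited by the authors were used as they stood, and no reads were aligned here. The wildtype table held 19884 genes in 12 libraries and the knockout table held 608 genes in 4 libraries. All values were whole numbers and were read as raw gene counts. Among the wildtype symbols, 27 that a spreadsheet had turned into dates were put back from their gene identifiers, 34 entries sharing a symbol were told apart by identifier, and 227 genes with 0 counts in every library were kept until the filter. Columns without a sample name held no counts and were not used. The totals of the knockout libraries cover only the listed genes, so their sequencing depths were not known here.

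The tests, samples, gene lists and alternatives were fixed before the data were examined, apart from those named below as chosen after seeing the data or the result. Wildtype tissues were compared with edgeR 4.0.16 in R 4.3.3 as 1 fit of 12 libraries, with TMM scaling, filterByExpr, quasi-likelihood tests and Benjamini-Hochberg adjustment over the 16641 genes tested. An adjusted p below 0.05 was the threshold. The knockout comparison joined the 608 listed genes of both tables and used TMM scaling over those genes alone, which left 563 genes tested. Fold changes there were therefore relative to the listed genes and not to the whole transcriptome. Genes called for a tissue or for both of 2 tissues had an adjusted p below 0.05 and a difference of at least 2-fold against each of the other groups. Levels are means ± SD of 4 libraries, in CPM (counts scaled by library size and TMM) for the wildtype tissues and CPM of the listed genes alone (listed-gene CPM) for the knockout comparison. Errors of a log2 fold change are standard errors.

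29 gene lists were fixed by biological role. They covered prolactin family hormones, trophoblast lineage markers, placental cathepsins, pregnancy-specific glycoproteins and CEACAMs, yolk sac endoderm, decidua and uterine stroma, uterine glands, uterine natural killer cells, red blood cells, endothelial cells, macrophages and microglia, neurons, synaptic receptors, neural progenitors, astrocytes, myelin, choroid plexus, serotonin and catecholamine enzymes, serotonin and dopamine receptors, hormones and their receptors, steroid synthesis, imprinted genes, nutrient transporters, cell cycle, hypoxia, immediate early genes, mitochondrially encoded genes, histone genes and sex chromosome genes. Members were counted as higher, lower or not past the test, with p adjusted over all genes and adjusted over the list alone. Whole lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation beside it. Over-representation of the lists among the 608 genes was tested with a 1-sided Fisher's exact test against genes expressed in the placenta. This test takes genes as independent draws. Members of a list that vary together, or a choice of the 608 genes by change in these libraries, would make its p-values too small.

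Named genes were the 10 largest changes in each direction per comparison among genes past the test, with at least 10 CPM in the higher group and every library of the higher group above every library of the lower group. Predicted genes were passed over. From each list up to 4 members with the smallest adjusted p and up to 2 members against the list's direction were added, and Foxa2 was added in every case. The uterine gland list and the serotonin and catecholamine list were taken whole. Where a group had 0 counts the fold is a floor computed from 3 counts per library, written as at least. Intervals of this kind cover counting error only, and p-values measure the spread between these samples. Genes of families with nearly identical copies, such as the prolactins, pregnancy-specific glycoproteins, cathepsins, serpins of the Serpinb9 group and globins, share reads, and counts of single members depend on how such reads were handled. Gene coordinates are those of GRCm38.

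Alternatives used RLE scaling, DESeq2 1.42.0, no filter, a filter at 5 CPM, only the 2 groups compared or all 16 libraries, the replicate number as a block, each library left out in turn, an adjusted p below 0.01, and 2-fold or 4-fold limits. Group labels were exchanged in all 35 splits of 8 libraries. A self-test planted changes in simulated counts. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures. Left out were isoforms, transcripts outside the tables, knockout genes beyond the 608, and sequence reads.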

Results

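The transcriptomes of placenta, fetal brain and maternal brain of wildtype mice on day 15 of pregnancy were compared with 4 libraries each, and 608 genes were compared between the placentas of wildtype and uterine FOXA2 cKO pregnancies. The wildtype libraries held 30323802 to 47182611 counts. In the placenta the most abundant transcript was Tpbpa, a marker of spongiotrophoblast, at 1.55% to 2.40% of all counts, while mt-Co1 led in all 4 maternal brains. Mitochondrially encoded transcripts made up 7.09% to 8.08% of counts in the maternal brain, 1.51% to 2.77% in the fetal brain and 1.80% to 3.50% in the placenta. The first principal component (71.9% of the variance) set the placenta apart from the brains and the next (25.5%) set the fetal brain apart from the maternal brain. At a mean of 1 CPM or more, 12132 genes were expressed in all 3 tissues, 941 in the placenta only, 213 in the fetal brain only and 460 in the maternal brain only. Brain transcripts in wildtype placenta replicate 4, described below, can raise the placenta mean of a brain gene past this limit. These counts were not made without that library.

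Wildtype placenta replicate 4 stood apart from the other placentas, with correlations of 0.967 to 0.972 to them, against 0.994 to 0.998 among fetal brains and 0.998 to 0.999 among maternal brains. It contained transcripts of neurons and glia. The synaptic vesicle gene Snap25 was at 45.1 CPM there and at 0.225 to 0.712 CPM in the other 3 placentas. Genes specific to the maternal brain, chosen for at most 1% of their brain level in placentas 1 to 3, were found in it at a median of 2.51% of that level. All tests below include this library unless it is said to be left out, and values without it are given for some of the genes and lists that it moved.

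**Figure D1:**
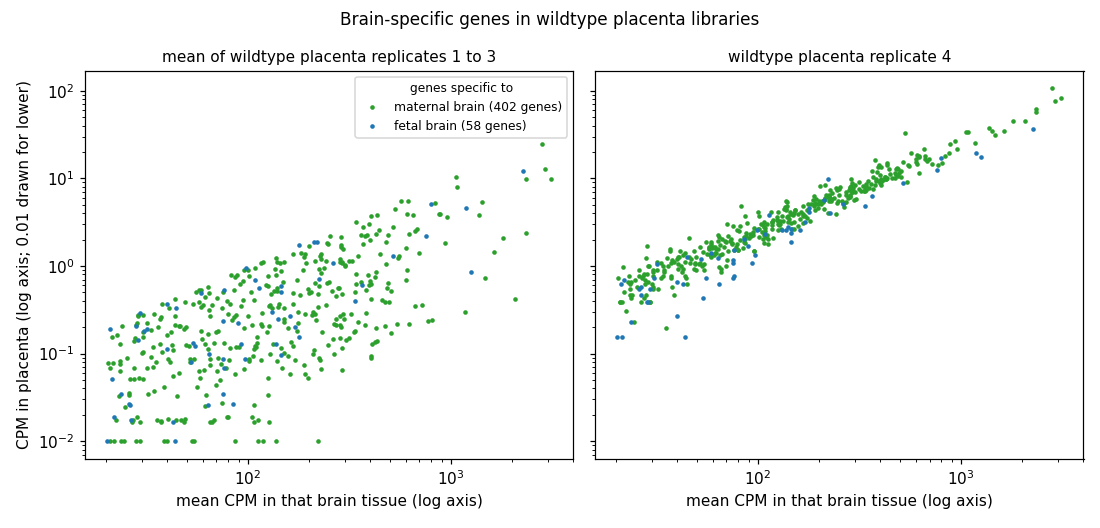
Level in the placenta (y, CPM) against level in the brain (x, CPM), log axes, for 402 genes specific to the maternal brain and 58 specific to the fetal brain, as the mean of placentas 1 to 3 (left, where genes were chosen to lie at 1% or less) and in placenta 4 (right). In placenta 4 the genes lay at 2.51% of the maternal and 1.77% of the fetal brain level.

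Prolactin, trophoblast and nutrient transporter genes were higher in the placenta than in the fetal brain, and neural progenitor genes were lower. Peg10, an imprinted gene of retrotransposon origin, was higher in the placenta by a log2 fold change of 4.70 ± 0.092 (7610 ± 926 against 292 ± 17.9 CPM, n = 4 per group, adjusted p = 1.92e-12). The trophoblast factor Hand1 was higher by 11.36 ± 0.33 (259 ± 27.1 CPM), and Flt1, which binds vascular growth factors, by 7.12 ± 0.18 (2960 ± 756 CPM). Emx1, a factor of the dorsal forebrain (chromosome 6, 85187438 to 85204462), was lower in the placenta (-8.56 ± 0.18, 28.0 ± 1.6 CPM in the fetal brain, adjusted p = 2.55e-12). Of 16641 genes tested, 6494 were higher and 7557 lower in the placenta, with 4373 and 4903 of them at least 2-fold apart. No other split of these 8 libraries gave more than 1 gene, against 14051 for the real one. The other splits mix the tissues, so this shows that the tissues differ and does not test the size of the count. The counts were 7017 and 6989 with RLE scaling and 7166 and 6774 with DESeq2, so which side held more genes depended on the scaling. The median log2 fold change was -0.122 with TMM and 0.00144 with RLE scaling, and 6 called genes changed sign between these.

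The largest differences towards the placenta were in genes without a count in the fetal brain. They were Mageb16 on the X chromosome (79623231 to 79671435), a MAGE family gene, at least 587-fold (37.5 ± 2.0 CPM), the prolactin gene Prl2c1 at least 427-fold (27.3 ± 6.13 CPM), the tripartite motif gene Triml2 at least 345-fold (22 ± 2.54 CPM), the adhesion gene Ceacam15 at least 310-fold and the secretoglobin Scgb1a1 at least 254-fold. The protease inhibitors Serpinb9c (log2 12.35 ± 0.36, 210 ± 29.9 CPM, adjusted p = 2.07e-11), Serpinb9d (12.61) and Serpinb9f (12.66 ± 0.34, 122 ± 22.6 CPM) followed. Prl3a1 (at least 420-fold, 26.8 ± 45.9 CPM) and the cathepsin Cts6 (12.45 ± 1.7, 614 ± 886 CPM) were also among the 10 largest, with most of their counts in placenta replicate 4 (95.5 and 1930 CPM). Towards the fetal brain the largest were Nkx2-1, which patterns the ventral forebrain (-10.43 ± 0.36, 43.7 ± 3.96 CPM, adjusted p = 9.09e-11), the cortical factor Fezf2 (-9.43 ± 0.42, 36.8 ± 1.9 CPM), the secreted signals Fgf15 (-9.33) and Wnt8b (-9.27), and the factors Neurog1 (-9.26), Sox14 (-9.08), Otx2 (-8.79, 75.3 ± 1.83 CPM), En1 (-8.65) and Tfap2d (-8.61). Nkx2-1, Fezf2, Fgf15, Neurog1 and En1 had 0 counts in placentas 1 to 3 and 2 to 7 counts in placenta replicate 4, so their fold changes rest on that library. Without it Otx2 was at -10.97, Sox14 at -9.72 and Tfap2d at -9.25.

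Every tested member of the prolactin family (24 of 24), the trophoblast markers (24 of 24), the placental cathepsins (7 of 7) and the pregnancy-specific glycoproteins and CEACAMs (21 of 21) was higher in the placenta than in the fetal brain. Examples were Prl2a1 (log2 11.53 ± 0.44, 824 ± 159 CPM), Prl2c2 (11.32 ± 0.35, 211 ± 49.8 CPM), Ctsj (11.67 ± 0.89, 6240 ± 1870 CPM), Ceacam3 (12.04 ± 0.41, 1290 ± 301 CPM) and Psg25 (12.14 ± 0.52, 1240 ± 434 CPM). The trophoblast list passed camera (adjusted p = 8.01e-15, and adjusted p = 0.032 with an estimated correlation). The prolactins had an adjusted p = 0.000223, and adjusted p = 0.133 with an estimated correlation. The glycoproteins had 0.000707, and adjusted p = 0.501 with an estimated correlation. The cathepsins had 0.0515, which became 0.0133 without placenta replicate 4, and adjusted p = 0.222 with an estimated correlation. These counts were the same adjusted over the list alone, as were those of the other lists in this comparison unless another count is given.

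Genes of the fetal membranes and of the maternal part of the placenta were also higher than in the fetal brain. Of 15 yolk sac markers 14 were higher, such as the apolipoprotein Apoa1 (log2 9.78, 407 ± 248 CPM) and the coactivator Cited1 (7.23, 306 ± 35.3 CPM), and placenta 1 stood below the others for this list (mean log2 CPM 4.91 against 6.71 to 7.40). The camera adjusted p was 0.0133, lost without placenta replicate 4 (0.0896) and without replicate 3 (0.0679), and adjusted p = 0.555 with an estimated correlation. Of 16 decidua and stroma markers 13 were higher and 2 lower (adjusted p = 2.71e-05, and adjusted p = 0.122 with an estimated correlation). The chaperone Cryab was at 7.41 (256 ± 26.3 CPM) and the progesterone receptor Pgr at 4.40 (43 ± 8.29 CPM), while Igfbp4 (-1.33) and the collagen Col1a1 (-1.13) were lower. Uterine natural killer cell markers were higher in 9 of 10, with the granzyme Gzmf at 10.77 (256 ± 90 CPM) and only Eomes, shared with cortical progenitors, lower at -4.34 (0.0402, adjusted p = 0.502 with an estimated correlation, and 0.0514 with RLE scaling). Endothelial markers were higher in 11 of 12, such as the cadherin Cdh5 (4.17 ± 0.14, 971 ± 160 CPM), and this list passed both ways (0.000707, and adjusted p = 0.0455 with an estimated correlation, which was 0.0829 without placenta replicate 4).

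Among uterine gland genes 10 of 12 were higher in the placenta than in the fetal brain and 1 was lower (camera adjusted p = 0.0156, and adjusted p = 0.156 with an estimated correlation). The log2 fold changes were 9.27 for the trypsin inhibitor Spink1, 9.18 for the keratin Krt18 (1490 ± 226 CPM), 6.37 for Foxa3, 5.88 for Lif (3.92 ± 0.363 CPM), 5.19 for lactoferrin (Ltf), 4.91 for the cadherin Cdh1 (200 ± 2.72 CPM), 4.87 for Sult1d1, 3.17 for the mucin Muc1, 1.73 for Wfdc3 and -2.45 for Foxa1. Foxa2 itself was at 4.98 ± 1.21 CPM in the wildtype placenta, 3.29 ± 0.324 CPM in the fetal brain and 0.174 ± 0.0468 CPM in the maternal brain, a log2 fold change of 0.60 (adjusted p = 0.0102) against the fetal brain and 4.81 (adjusted p = 2.62e-09) against the maternal brain. The thyroid hormone carrier Ttr did not pass (-0.34, adjusted p = 0.491).

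The placenta held more transcript for nutrient transport and steroid synthesis than the fetal brain. Nutrient transporters were higher in 22 of 23, such as the amino acid transporter Slc38a4 (log2 6.42 ± 0.18, 1330 ± 144 CPM), the glucose transporter Slc2a1 (3.42 ± 0.08, 862 ± 90 CPM) and the lactate transporter Slc16a1 (4.10), with camera adjusted p = 6.18e-08 and adjusted p = 0.117 with an estimated correlation. Steroid synthesis genes were higher in 12 of 14, led by Hsd17b2 (11.10, 147 ± 17.3 CPM) and the side-chain cleavage enzyme Cyp11a1 (9.68 ± 0.33, 208 ± 46.8 CPM), with Hsd17b1 lower (-1.95), and this list passed both ways (0.000552, and adjusted p = 0.0455 with an estimated correlation). Imprinted genes were higher in 17 and lower in 8 of 26, with Sfmbt2 at 6.34 and the neuronal Nnat at -5.86 (2020 ± 35.6 CPM in the fetal brain). Their adjusted p was 0.0488, 0.0511 with RLE scaling, and adjusted p = 0.501 with an estimated correlation. Hypoxia genes were higher in 11 and lower in 2 of 15, with the peptide Adm at 6.27 and the demethylase Kdm3a at -1.59 (0.00263, and adjusted p = 0.117 with an estimated correlation).

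Most neuron, synaptic and progenitor genes were lower in the placenta, and placenta replicate 4 moved with these groups and with glial genes. Neural progenitor markers were lower in all 18, such as the filament Nes (log2 -4.26, 523 ± 5.71 CPM in the fetal brain), Sox4 (-4.48) and Nhlh1 (-8.09), with adjusted p = 0.000116, and adjusted p = 0.501 with an estimated correlation, which was 0.00263 without replicate 4. Neuron markers were lower in 13 and higher in 1 of 16. The growth cone gene Stmn2 was at -6.23 ± 0.69, and at -7.46 without replicate 4. Synaptic receptors were lower in 19 and higher in 1 of 20, with Gria4 at -4.51, and at -5.26 without it. With all libraries neither list passed camera (0.262 and 0.226), and without replicate 4 both were lower (1.65e-10 and 1.77e-13), as were astrocyte markers (0.215, and 0.0113 without it). None of these 3 passed with an estimated correlation, with adjusted p = 0.797, 0.797 and 0.733 with all libraries and 0.104 for each without replicate 4. Astrocyte markers were lower in 7 and higher in 3 of 12, with Fgfr3 at -4.29 and Agt, the angiotensin precursor, at 7.44. Myelin genes were lower in 7 and higher in 2 of 14 (0.485), with Olig2 at -5.93, and at -6.86 without replicate 4. Mobp, a myelin protein gene, was higher (4.07 ± 1.4, adjusted p = 0.0195) only through replicate 4 and was at -0.35 (adjusted p = 0.536) without it.

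Serotonin and catecholamine genes divided between placenta and fetal brain, with 11 higher and 6 lower of 18 in the placenta (camera adjusted p = 0.233). The tryptophan-degrading enzymes Tdo2 (log2 7.15 ± 0.55, 32 ± 15.1 CPM, adjusted p = 1.31e-07), Ido1 (6.84) and Ido2 (1.44) were higher, as were the noradrenaline transporter Slc6a2 (7 ± 0.22, 236 ± 17.4 against 1.85 ± 0.665 CPM, adjusted p = 4.8e-11), the serotonin transporter Slc6a4 (1.32), the vesicle transporter Slc18a1 (4.39), the cofactor enzymes Gch1 (3.51) and Qdpr (0.18), and the breakdown enzymes Maoa (2.17), Maob (4.72 ± 0.49) and Comt (0.66). The enzymes of synthesis Tph2 (-4.52, and -6.11 without placenta replicate 4), Th (-2.33), Dbh (-5.30) and Ddc (-0.75) and the transporters Slc6a3 (-2.43) and Slc18a2 (-2.31) were lower. Tph1, which makes serotonin outside the brain, did not pass (1.46, adjusted p = 0.1, and 0.02 without placenta replicate 4). Serotonin and dopamine receptors were lower in 12 and higher in 3 of 17 (0.487), with Drd2 at -6.33 and Htr2b at 6.10 (10.1 ± 4.96 CPM). Drd2 and Dbh had counts in the placenta only in replicate 4, 2 each.

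The remaining lists did not pass camera between placenta and fetal brain. Cell cycle genes were lower in 19 of 20, such as Top2a (log2 -2.40 ± 0.3, 94.4 ± 35 against 497 ± 49.5 CPM) and Mki67 (-2.26 ± 0.26), and only Rrm2 was higher (0.74), with camera adjusted p = 0.183. Placenta replicate 4 was lowest for this list (mean log2 CPM 4.20 against 5.20 to 5.76). Hormones and their receptors were higher in 13 and lower in 10 of 27 (0.222), with the growth hormone releasing hormone Ghrh at 9.02 ± 0.36 (158 ± 49.4 CPM) and the thyroid receptor Thra at -4.02. Macrophage markers were higher in 7 and lower in 7 of 15 (0.24), with Csf1r at 5.03 and the microglial Cx3cr1 at -1.28. Choroid plexus genes were higher in 6 and lower in 4 of 12 (0.233), with the prolactin receptor Prlr at 4.26 and Msx1 at -3.85. Immediate early genes were higher in 10, and in 9 adjusted over the list alone, and lower in 3 of 16 (0.097), with Atf3 at 5.68. Red blood cell genes were higher in 6, and in 5 adjusted over the list alone, of 13 (0.589), with the adult globin Hbb-bs at 2.11 ± 0.44. Mitochondrially encoded genes were higher in 6 of 13 (0.589), with mt-Co1 at 0.79, and their mean log2 CPM differed between libraries, at 7.07 in placenta 1 and 10.1 to 10.8 in the others, and at 8.63, 6.87, 10.3 and 10.4 in fetal brains 1 to 4. Histone genes were higher in 3 and lower in 3 of 10 (0.641). The sex chromosome gene Ddx3y did not pass (-0.89, adjusted p = 0.682).

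**Figure D2:**
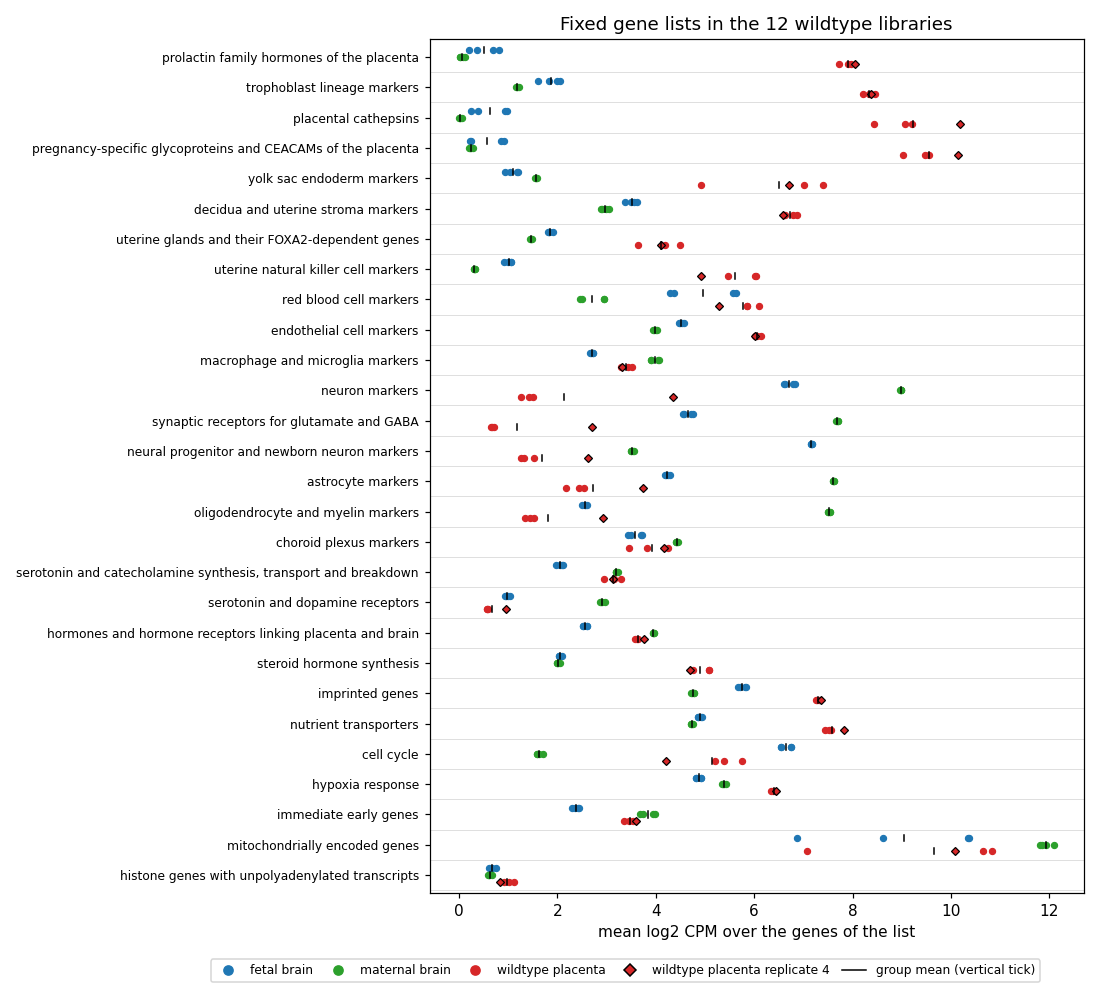
Mean log2 CPM over the genes of each of 28 lists (x) in each wildtype library, coloured by tissue, with placenta 4 as a diamond and ticks at the tissue means. Placental hormone and protease lists lay far to the right in the placenta, and neuron markers were at 4.35 in placenta 4 against 1.26 to 1.51 in the other placentas.

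Against the maternal brain the placenta differed in the same placental genes and in genes of neurons and glia. The homeobox gene Rhox6 was at 576 ± 46.9 CPM in the placenta (n = 4) and without a count in the maternal brain (at least 8210-fold). The amino acid transporter Slc38a4 was higher by a log2 fold change of 9.98 (1330 ± 144 against 1.31 CPM). The dopamine receptor Drd2 was lower (-9.81 ± 0.4, 15.5 ± 1.22 CPM in the maternal brain, adjusted p = 3.22e-10). Of 16641 genes 7237 were higher and 7214 lower, with 4719 and 5118 of them at least 2-fold apart. No other split of the 8 libraries gave any gene, against 14451 for the real one, which again shows only that the tissues differ. Other large differences were in Ctsj (17.33 ± 1.1, 6240 ± 1870 CPM), Cts3 (17.19, 4800 ± 2740 CPM), Ceacam5 (17.06, 4390 ± 2210 CPM), Ctsm (16.78), Psg28 (16.66), Ctsq (16.65) and Serpinb9g (at least 4170-fold, 292 ± 54 CPM). Cts6 (at least 8750-fold) and Prl8a6 (at least 4500-fold, 316 ± 408 CPM) had most of their counts in placenta replicate 4. Towards the maternal brain followed the potassium channel Kcnj6 (-9.05 ± 0.52), the kinase Plk5 (-8.41 ± 0.23, 35.2 ± 1.22 CPM), Fam19a1 (-8.61), Tceal6 (-8.52), Cntnap5b (-8.40), Dusp15 (-8.36), Hs3st2 (-8.33), Neu4 (-8.31) and the interneuron gene Lamp5 (-8.34, 112 ± 2.34 CPM). Drd2, Kcnj6, Fam19a1, Cntnap5b, Hs3st2, Neu4 and Lamp5 had 0 counts in placentas 1 to 3 and 2 to 46 in replicate 4, so their fold changes rest on that library, and without it Tceal6 was at -11.65 and Dusp15 at -10.50.

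The placental families were higher against the maternal brain in every tested member, 24 of 24 prolactins, 24 of 24 trophoblast markers, 7 of 7 cathepsins and 21 of 21 glycoproteins and CEACAMs. Examples were Prl2a1 (log2 16.51, 824 ± 159 CPM), Prl8a2 (16.04, 1760 ± 776 CPM), Peg10 (6.77 ± 0.1), Hand1 (13.63) and Psg25 (15.88). Their camera adjusted p were 0.000271, 1.97e-15, 0.0377 and 0.000927, and with an estimated correlation 0.482, 0.0748, 0.553 and 0.564, none past 0.05. The cathepsins lost their call without placenta replicate 3 (0.0653). Yolk sac markers were higher in 14 of 15 (0.0377, and adjusted p = 0.64 with an estimated correlation), with Apob at 13.53 (864 ± 653 CPM) and Ttr lower at -1.81 (203 ± 141 against 713 ± 14.8 CPM). Decidua markers were higher in 14 of 16 (7.08e-05, and adjusted p = 0.148 with an estimated correlation), such as the homeobox gene Hoxa10 (9.91, 64.3 ± 4.84 CPM) and decorin (Dcn, 4.61, 635 ± 91.4 CPM). Natural killer markers were higher in 9 of 10 (0.00673, and adjusted p = 0.553 with an estimated correlation), with Gzmf at 13.25. These counts and those of the other lists against the maternal brain were the same adjusted over the list alone.

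Gland, vessel and blood genes were higher in the placenta than in the maternal brain. Of 12 gland genes 10 were higher, Spink1 by a log2 fold change of 13.19, Krt18 by 9.52, Foxa3 by 9.38, Muc1 by 7, Cdh1 by 5.44, Foxa2 by 4.81, Ltf by 3.12, Lif by 3.11, Sult1d1 by 3.07 and Foxa1 by 1.87, while Ttr was lower and Wfdc3 did not pass (0.16, adjusted p = 0.64). The list had a camera adjusted p = 0.00607, and adjusted p = 0.193 with an estimated correlation. Endothelial markers were higher in 11 of 12, with Cdh5 at 5.96 and Kdr at 2.62, and passed both ways (5.09e-05, and adjusted p = 0.0449 with an estimated correlation). All 13 red blood cell genes were higher (0.254), with the embryonic globin Hbb-bh1 at 7.38 and Hba-a1 at 3.16.

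Cell cycle, steroid and transport genes were also higher against the maternal brain. All 20 cell cycle genes were higher, such as Rrm2, which makes deoxynucleotides (log2 7.27 ± 0.28, 245 ± 69.4 against 1.58 CPM), Top2a (6.49 ± 0.37) and Mki67 (5.35 ± 0.3), with adjusted p = 0.00109, and adjusted p = 0.636 with an estimated correlation, and with placenta replicate 4 again lowest among the placentas. Nutrient transporters were higher in 22 of 23 (2.28e-07, and adjusted p = 0.148 with an estimated correlation), with Slc7a7 at 4.30 and Slc2a3, a neuronal glucose transporter, lower at -1.32. Steroid synthesis genes were higher in 13 and lower in 1 of 14 (0.00111, and adjusted p = 0.086 with an estimated correlation), with Cyp17a1, which leads to androgens, at 10.75 (55.2 ± 18.5 CPM). Imprinted genes were higher in 19 and lower in 6 of 26 (0.000414, and adjusted p = 0.221 with an estimated correlation), with the growth inhibitor Cdkn1c at 7.18 (562 ± 76.2 CPM) and Ndn at -2.48. Hypoxia genes were higher in 9 and lower in 3 of 15 (0.107), with Adm at 5.38. Histone genes were higher in 7 and lower in 1 of 10 (0.464), with Hist1h4a at 6.44. Mitochondrially encoded genes were lower in 7 of 13 (0.173), with mt-Cytb at -1.32 (2950 ± 140 against 7380 ± 153 CPM). Immediate early genes were higher in 7 and lower in 7 of 16 (0.752), and Ddx3y did not pass (11.55, adjusted p = 0.0603, and 0.0424 without placenta replicate 4).

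Neuronal and glial genes were lower in the placenta than in the maternal brain, again with placenta replicate 4 nearest to the brain. All 20 synaptic receptors were lower (camera adjusted p = 0.0164, and adjusted p = 0.64 with an estimated correlation), with Gabbr1 at -5.21 (712 ± 4.83 CPM in the maternal brain) and Gria4 at -6.64 ± 0.44, and at -7.38 without replicate 4. All 16 neuron markers were lower (0.0774, and adjusted p = 0.682 with an estimated correlation), and without replicate 4 the list passed both ways (1.22e-14, and adjusted p = 0.0494 with an estimated correlation), with Eno2, a neuronal enolase, at -6.82 ± 0.59, and at -7.80 without it. All 14 myelin genes were lower (0.00356, and adjusted p = 0.553 with an estimated correlation), with Cnp at -5.21, and at -5.53 without it. Astrocyte markers were lower in 11 of 12 (0.0299, and adjusted p = 0.564 with an estimated correlation), with Gjb6 at -6.27, and at -7.02 without it, and Gja1 higher at 0.45. Without replicate 4 the synaptic, myelin and astrocyte lists also passed with an estimated correlation (0.0441, 0.00871 and 0.0085). Progenitor markers were lower in 10 and higher in 3 of 18 (0.47, and without replicate 4 0.00586, and adjusted p = 0.166 with an estimated correlation), with Neurod1 at -7.06, and at -10.51 without it, and Nes at 1.30. Macrophage markers were lower in 9 and higher in 5 of 15 (0.28), with the microglial P2ry12 at -4.59. Choroid plexus genes were lower in 8 and higher in 4 of 12 (0.867), with Kl at -4.57, and at -5.23 without it, and Aqp1 at 5.42.

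Receptor, hormone and monoamine genes differed in both directions between placenta and maternal brain. Serotonin and dopamine receptors were lower in 14 and higher in 2 of 17 in the placenta (camera adjusted p = 0.00607, and adjusted p = 0.553 with an estimated correlation), with Htr5a at a log2 fold change of -7.30, and of -8.17 without placenta replicate 4, and the cardiac and placental receptor Htr2b at 6.09. Hormones and receptors were lower in 18 and higher in 8 of 27 (0.173). The growth factor Igf2 (chromosome 7, 142650766 to 142666816) was higher by 4.35 ± 0.13 (2500 ± 109 against 123 ± 8.02 CPM), and Crhbp, which binds the stress hormone CRH, was lower at -6.88. Of 18 serotonin and catecholamine genes 5 were higher and 8 lower (0.47). Higher were Slc6a2 (6.18 ± 0.21), Slc18a1 (4.29), Tdo2 (3.74 ± 0.43), Gch1 (2.83) and Maoa (1.55). Lower were Tph2 (-7.28 ± 0.51, adjusted p = 4.5e-08, and -8.86 without placenta replicate 4), Dbh (-7.00), Slc6a3 (-6.05), Th (-3.37), Qdpr (-2.32), Ddc (-1.62), Slc18a2 (-1.24) and Comt (-0.80), and Tph1, Maob, Slc6a4, Ido1 and Ido2 did not pass.

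Between the brains, cell cycle and progenitor genes were higher on the fetal side and myelin, macrophage and monoamine receptor genes on the maternal side, by lists that passed camera at the preset correlation and not with an estimated correlation. The replication enzyme Top2a was at 497 ± 49.5 CPM in the fetal and 1.05 ± 0.458 CPM in the maternal brain (log2 8.89 ± 0.41, n = 4 per group, adjusted p = 1.87e-09). The newborn neuron gene Dcx was at 1260 ± 27.8 against 47.7 CPM. The myelin gene Mobp (chromosome 9, 120149707 to 120181484) was lower in the fetal brain (-11.58 ± 1.8, 0.38 ± 0.263 against 1170 ± 14.9 CPM, adjusted p = 8.9e-05). Of 16641 genes 6606 were higher and 6569 lower in the fetal brain, with 3348 and 4156 of them at least 2-fold apart. No other split gave any gene, against 13175 for the real one, which shows only that the 2 brains differ. Among the largest were the progenitor factor Dbx1, at least 403-fold (28.3 ± 1.3 CPM against 0), the RNA-binding Igf2bp1 (10.72 ± 0.37, 123 ± 4.3 CPM), Fgf15 (10.44), Hmga2 (8.93) and the mitotic genes Cdca5 (9.44), Depdc1a (9.43), Ska1 (8.83), Aurkb (8.45) and Casc5 (8.24). Lower were the cerebellar receptor Gabra6 (-12.47, 107 ± 6.04 CPM in the maternal brain), Gpr37l1 (-11.50), the astrocyte filament Gfap (-9.94 ± 0.87, 223 ± 4.86 CPM), Myoc (-9.93), Opalin (-9.64), Egr4 (-9.59), Agt (-9.34), Etnppl (-9.20) and Neu4 (at least 159-fold).

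Several lists were mostly higher in the fetal brain. All 20 cell cycle genes were higher, such as Mki67 (log2 7.62 ± 0.33, 451 ± 53.6 against 2.3 CPM), with camera adjusted p = 8.15e-08, and adjusted p = 0.559 with an estimated correlation. Progenitor markers were higher in 15 of 18, such as Nes (5.55 ± 0.16) and Sox4 (5.38), with 6.29e-05, and adjusted p = 0.559 with an estimated correlation. Imprinted genes were higher in 15 and lower in 6 of 26, such as Magel2 (3.29) and Cdkn1c (5.21) against Impact (-2.74), with 0.00985, and adjusted p = 0.559 with an estimated correlation. Histone genes were higher in 6 and lower in 2, and lower in 3 adjusted over the list alone, of 10 (0.664). Endothelial markers were higher in 5 of 12 (0.198), with Kdr at 2.06, and red blood cell genes in 9 of 13 (0.38), with Slc4a1 at 4.35. Nutrient transporters were higher in 12 and lower in 7 of 23 (0.717). Other lists of this comparison had the same counts adjusted over the list alone unless another count is given.

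Other lists were mostly lower in the fetal brain, some of them without passing camera. The spread in the tests between the brains came from all 12 wildtype libraries, placenta replicate 4 included. No list test between the brains was run without that library. Whether it kept lists such as neuron, synaptic receptor and astrocyte markers from passing was not tested. All 14 myelin genes were lower, such as Mal (log2 -7.77), with camera adjusted p = 0.00534, and adjusted p = 0.683 with an estimated correlation. Macrophage markers were lower in 13 and higher in 2 of 15, with P2ry12 at -2.92 ± 0.15 (0.00244, and adjusted p = 0.49 with an estimated correlation). Serotonin and dopamine receptors were lower in 15 and higher in 1 of 17, with Drd1 at -4.63 (0.0019, and adjusted p = 0.559 with an estimated correlation). Hormones and receptors were lower in 15 and higher in 5 of 27, with Thrb at -4.58 and Igf2 at 1.97 (483 ± 85.7 CPM), with 0.0019, and adjusted p = 0.479 with an estimated correlation. The prolactin receptor Prlr was at 42.2 ± 1.96 CPM in the maternal and 1.01 ± 0.259 CPM in the fetal brain (-5.39 ± 0.15). Mitochondrially encoded genes were lower in 7 of 13, with mt-Cytb at -1.52 (0.033, and adjusted p = 0.68 with an estimated correlation), and fetal brains 1 and 2 (mean log2 CPM 8.63 and 6.87) stood below fetal brains 3 and 4 (10.3 and 10.4) for this list. Synaptic receptors were lower in 19 of 20 (0.0965), with Grin2a at -5.41, and astrocyte markers were lower in 10 and higher in 1 of 12 (0.33), with S100b at -8.32. Neuron markers were lower in 10 and higher in 2 of 16 (0.38), with Nrgn at -6.99 and Tubb3 at 1.99. Choroid plexus genes were lower in 7 and higher in 3 of 12 (0.198), hypoxia genes lower in 8 and higher in 2 of 15 (0.109) and immediate early genes lower in 11 and higher in 4 of 16 (0.0965), with Egr1 at -4.74 and Ier2 at 1.25.

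Of 18 serotonin and catecholamine genes 15 were lower and 1 higher in the fetal brain (camera adjusted p = 0.00985, and adjusted p = 0.479 with an estimated correlation). The log2 fold changes were -7.10 for Ido1, -4.04 for Maob, -3.62 ± 0.18 for Slc6a3, -3.41 for Tdo2, -2.76 ± 0.34 for Tph2, -2.49 for Qdpr, -2.05 for Ido2, -1.69 for Dbh, -1.46 for Comt, -1.13 for Slc6a4, -1.04 for Th, -0.87 for Ddc, -0.82 for Slc6a2, -0.68 for Gch1 and -0.62 for Maoa. Only the vesicle transporter Slc18a2 was higher (1.07). Placental genes were low in both brains but often higher in the fetal brain, with 11 of 24 prolactins (0.38), 16 of 24 trophoblast markers (0.0965), 5 of 7 cathepsins (0.456) and 12 of 21 glycoproteins (0.456) higher, and 3 trophoblast markers and 1 glycoprotein lower. Fetal brains 3 and 4 stood above fetal brains 1 and 2 for these lists, with a mean log2 CPM of 0.982 and 0.935 against 0.377 and 0.249 for the cathepsins and 0.919 and 0.845 against 0.246 and 0.229 for the glycoproteins. Prl7a2 was at 2.52 ± 1.79 against 0.0648 CPM and Prl3b1 at 5.47 ± 3.97 against 0.238 CPM. Tpbpa had 247, 166, 600 and 712 counts in fetal brains 1 to 4. The source of these low placental transcripts was not tested, and fold changes of placental genes against the fetal brain rest on them. Decidua markers were higher in 8 and lower in 6 of 16 (0.985), with Col3a1 at 6.99 and Pgr at -4.24. Yolk sac markers were lower in 5 and higher in 2 of 15 (0.664). Natural killer markers were higher in 4, and in 2 adjusted over the list alone, of 10 (0.33). Steroid synthesis genes were higher in 4 and lower in 5, and lower in 4 adjusted over the list alone, of 14 (0.884).

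Of the gland genes 5 of 12 were higher and 4 lower in the fetal than in the maternal brain (camera adjusted p = 0.512). Higher were Foxa1 (log2 4.32), Foxa2 (4.21, adjusted p = 1.48e-08), Muc1 (3.83), Cdh1 (0.53) and Krt18 (0.34), and lower were Lif (-2.77), Ltf (-2.07), Wfdc3 (-1.57) and Ttr (-1.47). The Y-linked Ddx3y was higher in the fetal brain (at least 238-fold, adjusted p = 0.0433), with 1587 and 1602 counts in 2 of the fetal brains, at most 1 in the others and 0 in the maternal brains.

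Across the 3 tissues 3127 genes were higher in the placenta than in both brains, such as Peg10, Rhox6 and Slc38a4, 1533 in the fetal brain than in the other tissues, such as Emx1, Nes and Top2a, and 2581 in the maternal brain than in the other tissues, such as Drd2, Gfap and Mobp. At 4-fold these were 1829, 486 and 1377. In both brains over the placenta there were 3479 genes (2209 at 4-fold), such as Gria4 and Tph2. In placenta and fetal brain over the maternal brain there were 1711 (714 at 4-fold), such as Rrm2, Mki67 and Cdkn1c. In placenta and maternal brain over the fetal brain there were 1648 (787 at 4-fold), such as Ido1 and Maob. Brain transcripts in placenta replicate 4 can add genes to this class. Mobp met its limits, with a placental rise only through that library. Of the 402 genes specific to the maternal brain, 76 were higher in placenta replicate 4 than in the fetal brain. How many of them this class holds was not counted. The groups of each class share a control tissue. Simulated groups without any changed gene gave at most 1 gene in any class, a low number set by that design. Independent draws with the same numbers of calls gave 1240, 986, 1278, 1508, 949 and 1092 in the order above. With the shared libraries divided between the comparisons the counts were 3137 to 3150, 1439 to 1444, 2589 to 2594, 3069 to 3273, 1546 to 1560 and 1472 to 1481. Of 100 splits of the 12 libraries, the real one included, at most 4 gave as many genes as any class. The others that did kept 1 tissue whole, so this shows that tissues differ and does not test the size of a class. The highest other counts, 3257 for 1 tissue and 4307 for both of 2 tissues, came from a split that kept the placenta whole and mixed the brains.

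In the placentas of FOXA2 cKO pregnancies the target gene itself could not be followed, since Foxa2 (chromosome 2, 148042877 to 148046969) was not among the 608 genes and the deletion was in the uterus. Among abundant genes Inhba, which encodes the activin A subunit (chromosome 13, 16011851 to 16031621), rose by a log2 fold change of 1.07 ± 0.23 (1340 ± 257 against 640 ± 204 listed-gene CPM, n = 4 per group, adjusted p = 0.00938). Top2a (chromosome 11, 98992943 to 99024189) fell (-1.35 ± 0.28, 848 ± 98.3 against 2160 ± 861 listed-gene CPM, adjusted p = 0.00892). Of 563 genes tested 91 rose and 209 fell. How the 608 genes were chosen was not given in the sources used here. None lay between log2 fold changes of -0.534 and 0.0475, an empty interval that a choice by change in these samples would leave, so these counts are not independent evidence. The real split gave 300 genes and no other more than 81, which excludes nothing if the list was chosen on the real grouping. Scaling over the listed genes moved the share of rises, from 30.3% of calls to 18.2% with RLE, 26.3% with DESeq2, 56.7% with unscaled counts and 59.5% with zero placed in the empty interval, while the median log2 fold change went from 0.168 to 0.0879, 0.0881, 0.369 and 0.411.

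The number of genes depended on single libraries. Rises went from 91 to 214 without wildtype placenta 4, and to 44, 45 and 60 without wildtype placentas 1, 2 and 3, and to 33, 47, 41 and 58 without knockout placentas 1 to 4, such as Inhba, which kept its call in all of them. Falls went from 209 to 132 without knockout placenta 1 and stayed between 146 and 218 without any other library, such as Top2a, which lay at -1.57 to -1.10 in these fits.

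Genes that rose with every library left out in turn included the sulfatase Arsj (log2 1.96 ± 0.39, 3.89-fold, 31.7 ± 7.3 against 8.05 ± 2.93 listed-gene CPM, adjusted p = 0.00892), the interferon-inducible Ifi202b (1.87 ± 0.44, 144 ± 10.9 against 39.4 ± 26.7), the muscle genes Myoz2 (1.49 ± 0.28, 61.4 ± 9.9 against 21.7 ± 3.82) and Mybpc3 (1.26 ± 0.26), the platelet-activating factor receptor Ptafr (1.39 ± 0.34, 152 ± 29.7 against 58.2 ± 25.7) and the collagen Col6a5 (1.31 ± 0.32, 688 ± 146 against 276 ± 107). Vax2 (1.43, past in 1 of 8 such fits), Asb16 (1.70, in 2) and Aoc3 (1.20, in 2) rose only with all libraries or a few of these fits. Htr2b, a serotonin receptor, rose by 0.81 but passed in 1 of 8 fits, and the imprinted protease inhibitor Tfpi2 by 0.55 in 3 of 8. Among macrophage markers Cd68 rose by 0.26 (adjusted p = 0.0494), past in 2 of 8 fits.

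Cell cycle genes fell in all 9 listed members, and in all 9 adjusted over the list alone. They were Aurka (log2 -1.57 ± 0.37, 118 ± 23.8 against 351 ± 167 listed-gene CPM, adjusted p = 0.0122), Plk1 (-1.51), Ccna2 (-1.50), Ccnb2 (-1.46), Ccnb1 (-1.44), Cdc20 (-1.41), Top2a, Aurkb (-1.34) and Cdk1 (-1.26). 9 of the 20 cell cycle genes expressed in the placenta were listed with lower values where 0.281 would be expected (exact adjusted p = 1.54e-10). Exact p-values here and below take genes as independent, and for this list camera estimated a correlation of 0.729 between placenta and fetal brain. Placenta 4 of the wildtype lay with the knockout placentas for this group, and without it Top2a was at -1.57, Aurka at -1.82 and Ccna2 at -1.77. The linker and core histone list had no tested member, and Hist1h2br, a core histone gene outside it, fell (-3.24 ± 0.78, adjusted p = 0.0131).

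Of 3 embryonic globin genes 2 fell, and adult ones went in both directions. The embryonic Hbb-bh1 (chromosome 7, 103841637 to 103843164) fell (log2 -3.33 ± 0.83, 142 ± 56.8 against 1430 ± 1470 listed-gene CPM, adjusted p = 0.015), and was at -3.70 without wildtype placenta 4. Hba-x fell (-2.19, past in 4 of 8 fits), as did the adult Hba-a2 (-1.87, in 2 of 8), which shares reads with Hba-a1. Hba-a1 rose by 0.85 ± 0.2 (21900 ± 4110 against 12100 ± 1930, adjusted p = 0.0118), in all 8 fits. Hbb-y (-1.44, adjusted p = 0.0539) and Hbb-bs (0.61, adjusted p = 0.193) did not pass, and without wildtype placenta 4 they were at -1.77 (0.0016) and 1.07 (0.00824). The ratio of Hbb-y to Hbb-bs counts was 0.465 to 0.743 in the knockout placentas. It was 3.53 to 6.92 in wildtype placentas 1 to 3 and 0.307 in wildtype placenta 4. Whether the groups differed in the stage of the conceptus was not tested. Of 6 red blood cell genes 1 rose and 3 fell, and 1 and 4 adjusted over the list alone. 4 of 13 were listed with lower values (exact adjusted p = 0.00071).

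Trophoblast genes changed in both directions, and with all libraries prolactins fell or did not pass. The fusion gene Syna of the labyrinth fell (log2 -0.70 ± 0.12, 991 ± 65.1 against 1610 ± 240 listed-gene CPM, adjusted p = 0.00805), in all 8 fits. Elf5, which keeps trophoblast stem cells (chromosome 2, 103411688 to 103450989), fell (-2.16, past in 3 of 8 fits), and Cdx2 rose by 0.31 (in 2 of 8). Of 7 prolactins 4 fell and none rose. Prl3d3 was at -1.89, Prl6a1 at -1.71, Prl7a1 at -1.24 (9950 ± 1010 against 23400 ± 12200) and Prl4a1 at -1.08, each past in 1 or 2 of 8 fits. Without wildtype placenta 4, 3 prolactins rose, Prl3a1 by 4.02 (adjusted p = 0.00355), Prl8a6 by 2.09 and Prl3c1 by 0.93, as did the cathepsin Cts6 by 2.53, Psg16 by 1.96, Psg26 by 1.81, Psg23 by 1.14 and Ceacam15 by 0.57. With it none of these passed, and of 5 glycoproteins and CEACAMs only Ceacam9 fell (-2.08, in 3 of 8 fits). Among the listed genes with lower values were 4 of 24 prolactins (exact adjusted p = 0.00624), and among those with higher values 4 of 21 glycoproteins and CEACAMs (0.0144).

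Hormone and steroid genes changed in few fits. Hsd11b2, which inactivates glucocorticoids, fell (log2 -1.51, 637 ± 69.7 against 1810 ± 973 listed-gene CPM, adjusted p = 0.024, in 2 of 8 fits), and the steroid enzyme Hsd3b6 fell too (-1.45, in 1 of 8), while Sult1e1, which inactivates estrogen, did not pass (0.39, and 0.83 with adjusted p = 0.0096 without wildtype placenta 4). The interleukin receptor Il11ra1, the only 1 of 4 decidua genes to change, fell (-0.70, in 2 of 8), and 3 of 16 decidua genes were listed with higher values (exact adjusted p = 0.045). Lactate transporter Slc16a3 (0.19), glucose transporter Slc2a3 (0.22), the hypoxia genes Vegfa (0.22) and P4ha1 (0.20), the endothelial Robo4 (0.26), the immediate early gene Fosb (0.49), which passed adjusted over the list alone, and the choroid plexus genes Aqp1 (0.36) and Slc4a5 (0.44) did not pass. Without wildtype placenta 4 Slc2a3 (0.51, adjusted p = 0.00158), Slc4a5 (0.60, 0.0107), P4ha1 (0.30, 0.0149), Vegfa (0.31, 0.0221) and Fosb (0.53, 0.0468) rose, and Cd68 no longer did (0.23, 0.0602). No member of the gland, yolk sac, natural killer, astrocyte, myelin, serotonin synthesis or mitochondrial lists was tested. The Y-linked Ddx3y (2.33) and Uty (2.32) did not pass, and 2 of 4 sex chromosome genes were listed with higher values (exact adjusted p = 0.032), with 1786 to 3440 counts of Ddx3y in 3 of 4 knockout placentas and 1351, 0, 0 and 16 in the wildtype placentas. Both genes lie on the Y chromosome and are not independent draws. By these counts fetal sex was not balanced between the groups, and it was not separated from genotype in this comparison.

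With all libraries the deepest named falls were in neuronal genes, and wildtype placenta 4 moved with those named here. Without it Hbb-bh1 (-3.70), Hist1h2br (-3.25), Hba-x (-2.55) and Elf5 (-2.49) lay in the range of these genes (-3.75 to -2.18). Of 2 neuron markers Syt1 fell and Tubb3 did not pass (0.36, adjusted p = 0.14), and Tubb3 rose without that library (0.60, adjusted p = 0.000798). Sept3, a neuronal septin, fell (log2 -6.94 ± 1.7, 0.681 ± 0.519 against 95.4 ± 170 listed-gene CPM, adjusted p = 0.0149), and was at -3.75 without that library. Nsg2, of the neuronal endosome, fell (-4.99 ± 1.2, and -2.76 without it), as did the cortical factor Tbr1 (-4.10 ± 1.1, and -2.18 without it), all in every fit. The glutamate receptor gene Gria2 fell (-6.16, past in 6 of 8 fits, and -2.88 without it), as did the calcium pump Atp2b2 (-5.81, 4 fits, -2.52), the vesicle calcium sensor Syt1 (-5.61, 5 fits, -2.24), Faim2 (-4.87, 4 fits, -2.27), the adhesion gene Chl1 (-4.67, 5 fits, -2.56) and the kinase Pak3 (-4.38, 7 fits, -2.22). Of the tested genes 56 were restricted to brain among the wildtype tissues, and 46 of these fell, all of which still fell without placenta 4, with a median of -2.21 with it and -1.73 without it. The list held 85 such genes, and the others were not tested. A gene with few knockout counts could pass the filter only through the wildtype placentas. This favours falls, as would a choice of the list by change, so these counts are not independent evidence. Gria2, Syt1 and Tbr1 had at most 44 counts in each of wildtype placentas 1 to 3, so their falls without placenta 4 rest on few reads.

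**Figure D3:**
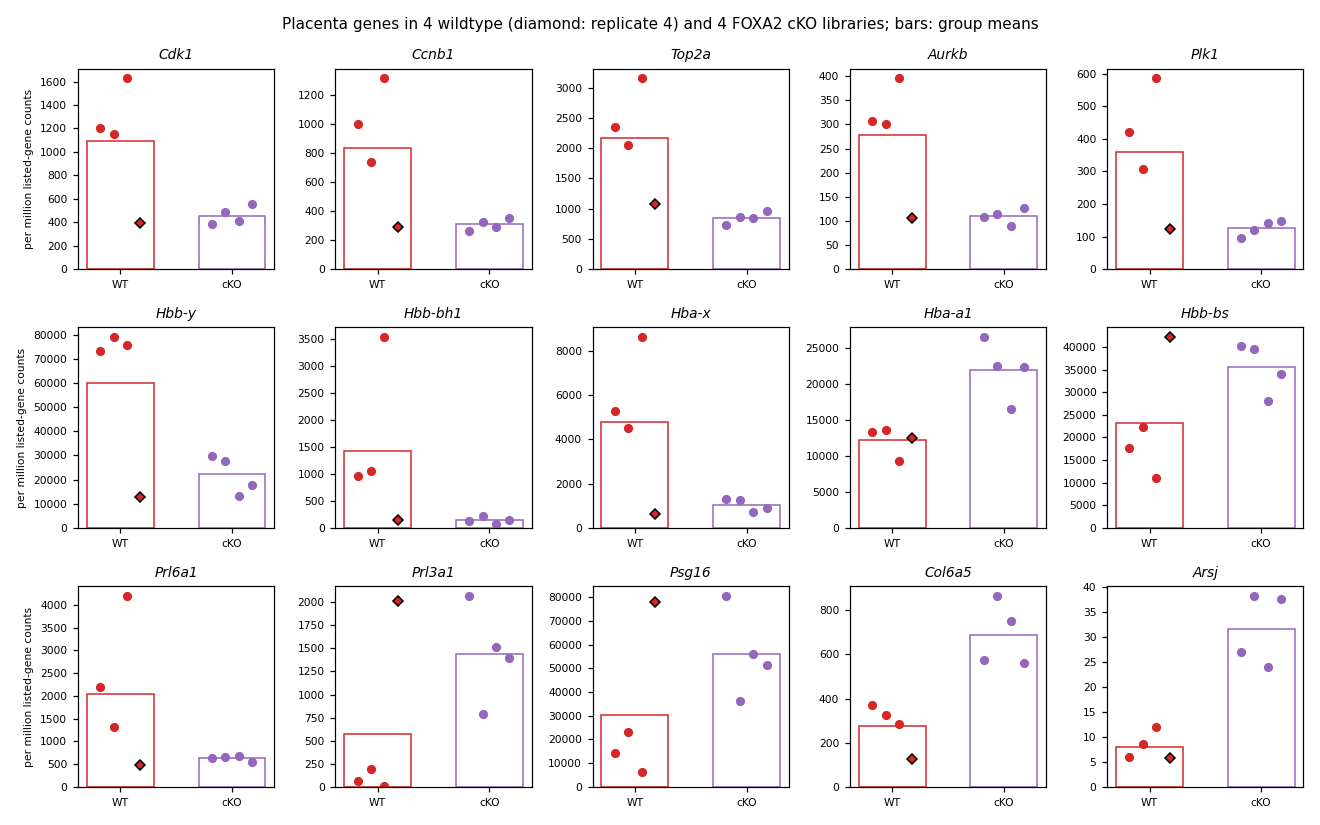
Listed-gene CPM of 15 genes in 4 wildtype (replicate 4 as a diamond) and 4 FOXA2 cKO placentas, with bars at the group means. Top2a fell from 2160 to 848 and was at 1075 in wildtype replicate 4.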

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

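The patterns below were found in the data, and the tests on them were chosen after seeing the result. In each group of 4 libraries, a library was picked out when its gap to the nearest other exceeded 0.829 of the group's range, a limit that chance passes in about 1 of 20 groups. This was asked of 226 groups of totals, list means and named genes. Wildtype placenta 4 was picked out for neuron markers (mean log2 CPM 4.35, others 1.26 to 1.51), synaptic receptors (2.70, others 0.641 to 0.719), myelin genes (2.92, others 1.34 to 1.52) and serotonin and dopamine receptors (0.96, others 0.574 to 0.584). In CPM it stood out for Mobp (25.4, others up to 0.422), Gfap (6.20, up to 0.591), Gpr37l1 (5.54, up to 0.141), Gabra6 (2.28, up to 0.0491), Lamp5 (1.78, others 0), Prl3a1 (95.5, up to 8.47), Prl8a6 (922, up to 166) and Cts6 (1930, up to 264). In listed-gene CPM it stood out for Syt1 (657), Gria2 (429), Nsg2 (407), Sept3 (350), Atp2b2 (305), Faim2 (255), Chl1 (159), Pak3 (134), Tbr1 (82.3) and Vax2 (32.6, others 9.84 to 11.9). Outside the placenta only Sox14 in fetal brain 3 (17.9 CPM), Ska1 in fetal brain 1 (14.1 CPM) and Hs3st2 in maternal brain 3 (22 CPM) were picked out.

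Brain transcripts in wildtype placenta 4 had adult and fetal features. Fetal brain RNA as the only source was excluded, since the excess of maternal-brain genes such as Mobp was 18.7 times that of fetal-brain genes when set against fetal brain levels. Maternal brain RNA alone was excluded too, since fetal-brain genes lay at 5.5 times the level it gives. RNA or reads of both brains, at 2.16% maternal and 1.32% fetal, put 96.3% of 375 genes kept out of the fit within 2-fold of their measured excess, so the values needed for it are there. Whether the mixing took place in tissue, RNA or libraries was not tested.

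Without wildtype placenta 4, 149 listed genes outside the brain-restricted set separated the groups by at least 2-fold. At 123 of these, such as Top2a and Hbb-bh1, wildtype placenta 4 lay nearer the FOXA2 cKO mean. Dilution by brain RNA was excluded, since the 20 cell cycle genes were at a median log2 of -1.4 against placentas 1 to 3 where that share can give at most -0.0511. A knockout library under a wildtype label remained open. Of the 149 genes 17.4%, such as Col6a5 and Arsj, were nearer the wildtype. The 6.04% at most for knockout libraries left out in turn cannot be set beside this. Those libraries took part in choosing the genes, and wildtype placenta 4 did not. For a later stage of the conceptus or another sampled part of the placenta, 1 of 2 values set for it was met. The ratio of Hbb-y to Hbb-bs was 0.307, below the 3.53 to 6.92 of placentas 1 to 3. Hbb-bh1 made up 1.09% of Hbb-y, outside the 0.417% to 0.796% of the knockout placentas that had been set. This share was still below the 1.33% to 4.69% of placentas 1 to 3, so the missed range does not speak against a later stage. This explanation stayed open, and these explanations cannot be told apart here.

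Brain-restricted transcripts such as Sept3, Gria2 and Syt1 fell in the knockout placentas even without wildtype placenta 4. Gria2 had 33, 11 and 15 counts in wildtype placentas 1 to 3 and 2, 2, 1 and 6 in the knockout placentas. Syt1 had 27, 15 and 44 against 6, 1, 6 and 12, so these falls rest on few reads. Carry-over of brain libraries into wildtype placentas 1 to 3 was excluded, since the largest share that 436 unlisted brain genes allow gives 3.52% of the level found. The scaling settings run moved the median of all listed genes only from 0.168 to between 0.0879 and 0.411, far less than the median of -1.73 of these genes, but a scaling from the depths themselves stayed open, since the depths were not known and the genes were picked for their fall. An effect of uterine FOXA2 or of LIF on these transcripts stayed open too and was not tested.

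Exchanging labels gave the real number of genes in 1 of 35 splits for placenta against fetal brain, 1 of 35 for placenta against maternal brain, 1 of 35 for the brains, and 1 of 35 for the knockout comparison, where this excludes nothing if its genes were chosen on the real grouping. Between the tissues the other splits mix tissues, so they do not test the size of a count. For the classes of genes, such as those of Peg10 or Nes, 2 of 100 splits gave as many for the placenta, 4 for the fetal brain, 2 for the maternal brain, 2 for both brains, 4 for placenta with fetal brain, and 4 for placenta with maternal brain.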

How the results depend on the processing

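Among named genes past the test 1 changed direction (Mobp, placenta vs fetal brain), at 4.07 with all libraries, -0.354 without wildtype placenta 4 and 4.57 without fetal brain 3. Among all genes 6 called between placenta and fetal brain changed sign with RLE, as did 6 of 563 in the knockout comparison with RLE or DESeq2. Requiring 2-fold left 4903 of 7557 genes lower in the placenta than in the fetal brain, 4719 of 7237 higher than in the maternal brain, 3348 of 6606 higher and 4156 of 6569 lower in the fetal than in the maternal brain, and 13 of 91 rises in the knockout. The 4-fold limit left 1829, 486, 1377, 2209, 714 and 787 genes in the tissue classes, and a filter at 5 CPM left 2074 for the placenta and 1032 for placenta with maternal brain. With an estimated correlation 3 of 13, 1 of 17 and 0 of 9 lists stayed past camera in the 3 tissue comparisons, and 4 and 7 passed against the fetal and the maternal brain with wildtype placenta 4 also left out, a setting chosen after seeing the data.

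In the knockout comparison the 91 rises became 47 with RLE, 11 at an adjusted p below 0.01, 290 with gap-centred scaling, 204 with unscaled counts and 337 with gap-centred scaling without wildtype placenta 4. The last 3 settings were chosen after seeing the data. The 209 falls became 81 at an adjusted p below 0.01. Leaving out 1 library gave 33 to 214 rises and 132 to 218 falls, 6397 to 6752 genes higher and 7446 to 7933 lower against the fetal brain, 7201 to 7490 and 7059 to 7474 against the maternal brain, and 6407 to 6488 and 6268 to 6381 between the brains. The cause of these changes was not tested. Of 61 named knockout genes 38 lost or gained a call in at least 1 such fit, against 4 of 161 for placenta and fetal brain, 4 of 158 for placenta and maternal brain and 6 of 165 for the brains.

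Libraries with the same replicate number had correlations of deviations from -0.213 to 0.376 in the knockout comparison and from -0.0447 to 0.114 between the tissues. Low values cannot exclude that such libraries came from 1 pregnancy. Ddx3y had 1587, 0, 1 and 1602 counts in fetal brains 1 to 4 and 1351, 0, 0 and 16 in wildtype placentas 1 to 4. Pairing of the libraries therefore stayed open. The replicate block gave 32 rises and 125 falls in the knockout comparison, and 6407 and 7539, 7152 and 7201, and 6531 and 6468 genes in the tissue comparisons. In the self-test edgeR found 83.6%, 83.6%, 88.1% and 71.6% of the 2-fold changes, and DESeq2 found 88.1%, 91%, 92.5% and 76.1%. Over all planted folds, false calls were 3.75%, 2%, 4.71% and 2.16% with edgeR and 22.3%, 17.2%, 24.9% and 5.26% with DESeq2. The self-test changed 200 genes, far fewer than were called between the tissues.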

Other observations

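Embryonic globin was found outside the placenta. Hbb-y, of primitive red blood cells, had 47792 to 135884 counts in the fetal brains and 2091, 32, 10 and 1810 counts in maternal brains 1 to 4. The ratio of Hbb-y to the adult Hbb-bs was 7.07 to 8.56 in the fetal brains, where Hbb-bh1 made up 1.32% to 1.43% of the Hbb-y counts, with 1.33%, 1.33%, 4.69% and 1.09% in wildtype placentas 1 to 4 and 0.417% to 0.796% in the knockout placentas. Tpbpa, at 662188 to 840504 counts in the placentas, had 247, 166, 600 and 712 counts in fetal brains 1 to 4 and 4, 45, 11 and 23 in maternal brains 1 to 4.

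The Y-linked genes Ddx3y and Uty varied between libraries of the same tissue. Ddx3y had 1587, 0, 1 and 1602 counts in fetal brains 1 to 4, 1351, 0, 0 and 16 in the wildtype placentas and 2036, 0, 1786 and 3440 in the knockout placentas. Uty had 855, 0, 0 and 1024, then 343, 0, 0 and 4, then 493, 0, 403 and 955 counts in the same libraries. Maternal brains had 0 counts of Uty.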
